A study of Rattus norvegicus with 15 samples.

How the data were processed

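RNA of the paraventricular hypothalamic nucleus (PVN) of rats was sequenced in 15 libraries, 5 in each of 3 groups. The groups were untreated rats (Control), rats under immobilization stress (Model) and rats given minocycline with immobilization stress (Minocycline). Groups and replicate numbers were taken from the labels. The labels do not tie the libraries to separate animals in words, so p-values measure the spread between these libraries.

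The authors deposited one table of FPKM (fragments scaled to gene length and to the fragments assigned in the library) for 24160 genes, with an Ensembl gene identifier and a gene symbol per row, per the file headers. Libraries were prepared from total RNA with a NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name fastp 0.22.0, HISAT2 2.1.0 and HTSeq 0.9.1. The genome build, the gene annotation and the strand setting are not given in the sources used here, so no gene positions are printed, and reads of overlapping or antisense genes cannot be told apart. Near-identical copies, such as metallothionein, haemoglobin, ribosomal protein and RT1 genes, can share reads, and their values are uncertain for that reason.

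The FPKM values were whole multiples of the worth of a single read, so the reads behind them were recovered from the table. All 21647 genes above 0 in at least 2 libraries gave whole reads within a tolerance of 0.05 reads, and 1391 genes were above 0 in 1 library only. Recovered reads ranged from 22385818 in Model replicate 5 to 36703753 in Minocycline replicate 5. They made up at least 99.9931% of the total the FPKM scale implies. A floor of 3 reads in a gene of 1 kilobase corresponded to between 0.0817 and 0.134 FPKM, and floors cover counting error only. The recovery was tested on simulated values, in which 99.9649% of 5705 genes returned their exact reads.

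Symbols were those of the table, which gives one for 17600 genes. A RefSeq gene table of assembly GRCr8 gave a name for 386 of the 6560 rows without a symbol, and none of its coordinates were used. A symbol with more than 1 row was read from the row with the highest mean FPKM.

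Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a pseudocount of 1. Genes with at least 1 FPKM in at least 5 of the 15 libraries were tested, which kept 14509 genes holding 99.734% of the recovered reads. All 15 libraries entered one fit with a mean-variance trend and no covariate. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and tests were two-sided. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Simulated data with known changes, drawn with the means and spreads of the real genes, were put through the same tests. For Model against Control, 96% of genes changed 2-fold and 71% of genes changed 1.5-fold were recovered, with 8 false calls among 14326 genes. For Minocycline against Model these shares were 91% and 74%, with 7 false calls. For Minocycline against Control they were 95% and 77%, with 10 false calls among 14336 genes. The simulated genes varied independently of each other, without the tissue differences between real libraries. Changed genes were drawn only from those with a mean above 2 FPKM. These shares and false calls therefore need not hold for the real libraries.

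Of 33 gene lists fixed beforehand, 30 had at least 5 tested members and were tested with camera at its preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list moves one way on balance, stand beside it. The list of mitochondrially encoded genes matched no row because the table writes those symbols without a prefix, and lists of 13 mitochondrial and 16 cardiac muscle genes were added after the values had been seen. A list score is the mean log2(FPKM + 1) of the tested members in a library. Scores were compared by exact permutation tests, two-sided, whose smallest possible p for 5 against 5 libraries is 0.0079. They were adjusted over the lists of a comparison, the added ones included.

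Named genes followed a rule fixed before the data were examined, as were the design, the lists and the first set of alternatives. The rule took the 10 highest and 10 lowest fold changes among called genes with a symbol. Where fewer than 10 genes passed, those with the smallest unadjusted p were added up to 10. It also took up to 4 members of each list by p, and 14 genes named in every comparison. Genes outside the rule are said to be so. P2ry12, one of the 14, is not analysed here.

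The alternatives fixed then were a pseudocount of 0.1, a filter at 0.1 FPKM, no filter, median-of-ratios scaling, quantile normalization, a fit on the 2 groups compared, a replicate block, array weights, robust moderation and leaving out each of the 15 libraries. Chosen after seeing the data were voom on the recovered reads, a thalamus marker score as a covariate, and leaving out libraries with low thalamus markers or with cardiac transcripts. Leaving out the latter kept only Minocycline replicates 1 and 3 in their group, so results of that setting rest on few libraries. Chance values for comparisons that share libraries came from 100 random deals of the residual libraries. A first form of that simulation allowed a dealt group to coincide with a real one, which gave degenerate values in some deals, and it was replaced by deals that keep at most 3 of 5 libraries of any group together.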

Results

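Bulk RNA of the rat PVN, the hypothalamic nucleus that holds the neuroendocrine neurons of the stress axis, was measured in 15 libraries. The series asks what microglia of this nucleus contribute to stress cardiomyopathy, with minocycline, a tetracycline antibiotic used to inhibit microglia, given to 1 of the stressed groups. Control, Model (immobilization stress) and Minocycline (minocycline with immobilization stress) had 5 libraries each. Recovered depth ranged from 22385818 to 36703753 reads per library. Correlations of log2(FPKM + 1) between libraries lay between 0.96 and 0.987.

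The first comparison, Model against Control, asks what immobilization stress changed in the PVN. Fkbp5 (ENSRNOG00000022523), a co-chaperone of the glucocorticoid receptor, rose from 13.1 ± 2.64 FPKM in Control to 29.7 ± 3.23 in Model (SD, n = 5 each; log2 fold change 1.14, SE 0.125, limma adjusted p = 0.000477). Mt2A (ENSRNOG00000043098), a metal-binding metallothionein, rose from 27.8 ± 4.18 to 82.4 ± 10.9 FPKM (log2 fold change 1.54, limma adjusted p = 5.52e-05). Mfsd2a, a lipid transporter of the blood-brain barrier, rose from 14.9 ± 1.71 to 29.8 ± 3.52 FPKM (limma adjusted p = 0.000378). In all, 53 of 14509 tested genes were called, 31 higher and 22 lower in Model. At an unadjusted p under 0.05 there were 2126 genes, where chance gives 725.

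The other genes with the highest fold changes were Pla2g3, a secreted phospholipase, at 2.23, Rpph1, the RNA of ribonuclease P, at 1.32, and Lrg1, an acute-phase glycoprotein, at 1.15 on the log2 scale. Gpatch4 followed at 0.97, then the cold-inducible RNA-binding protein Rbm3 and the small heat shock protein Cryab at 0.78 each, and the corepressor Hr at 0.73. Lowest were Mia at -1.08, Prom1 at -0.98, and the transporters Slco1c1 at -0.89 and Slco2b1 at -0.84. Ninj2 stood at -0.83, Adpgk at -0.81, LOC685203 at -0.78, the cyclin Ccnd1 at -0.77, Tjap1 at -0.74 and the oligodendrocyte protein Opalin at -0.69. Each of these 20 genes moved the same way in all 5 Model libraries relative to the Control mean. Fkbp5, Mt2A and Mfsd2a passed in all 28 alternatives. Cryab, Lrg1 and Slco1c1 passed in 10, Gpatch4 in 12, Hr in 13, Ccnd1 and Opalin in 14, and the other 10 in 19 to 27. Leaving out any 1 library other than Control replicate 4 or Minocycline replicate 5 moved the count by over 1.5 times, to 195 genes without Model replicate 3 and to between 19 and 35 without each of the others. Of those 195 genes, 61 were higher and 134 lower in Model, so the balance turned to mostly lower. Model replicate 3 had a thalamus marker score of 3.23, against 4.52 to 5.02 in the other Model libraries.

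**Figure D1:**
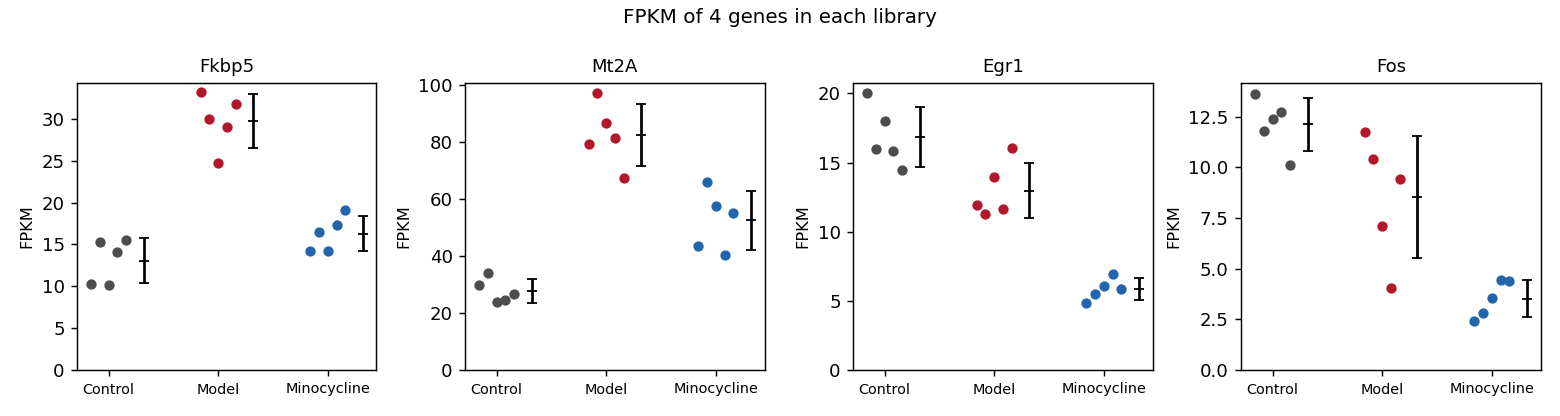
FPKM of Fkbp5, Mt2A, Egr1 and Fos (y axes, from 0) in each library of the 3 groups, with points for libraries and bars for the mean and SD of 5. Fkbp5 means were 13.1 in Control, 29.7 in Model and 16.3 in Minocycline, and Egr1 means were 16.9, 12.98 and 5.85.

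Among the fixed lists, 22 of 23 glucocorticoid-responsive genes had a positive fold change in Model, with a median of 0.39 (camera adjusted p = 1.09e-11, but adjusted p = 0.494 with an estimated correlation). Mt2A and Fkbp5 were called over all genes, and 8 members were called higher adjusted over the list alone. Plin4, a lipid droplet protein, stood at 0.811 ± 0.183 FPKM in Control and 2.45 ± 1.09 in Model (limma adjusted p = 0.0688). The list score was 0.48 higher in Model (SE 0.15, exact permutation p = 0.024, adjusted p = 0.25), and 3 of 5 Model libraries lay above every Control library. The median of the glucocorticoid-responsive genes was 0.23 without the 5 libraries with low thalamus markers. Of 15 oligodendrocyte markers, 12 had a negative fold change, with a median of -0.32 (camera adjusted p = 0.000192, but adjusted p = 0.813 with an estimated correlation). Opalin was called, and 7 members were called lower adjusted over the list alone. Ugt8, a myelin lipid enzyme, stood at 44.8 FPKM in Control and 22.3 in Model (limma adjusted p = 0.0731). Without the same 5 libraries the oligodendrocyte median was -0.14.

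Further lists called by camera were oligodendrocyte precursors (median -0.26, adjusted p = 0.0365), heat shock and unfolded protein response (median -0.17, adjusted p = 0.00274), nuclear oxidative phosphorylation subunits (median 0.11, adjusted p = 5.46e-08) and cytosolic ribosomal proteins (median 0.10, adjusted p = 4.95e-05). With an estimated correlation the adjusted p of these 4 lists was 0.813. They passed in 19, 27, 28 and 24 of 28 alternatives. Model replicate 2 had the highest scores among Model libraries for oxidative phosphorylation (6.65, the others 6.22 to 6.41) and ribosomal proteins (7.50, the others 7.03 to 7.33). Without it the medians of nuclear oxidative phosphorylation subunits and cytosolic ribosomal proteins were 0.040 and 0.0101, and the ribosomal list was not called (camera adjusted p = 0.331). No list passed with fry, whose adjusted p for the glucocorticoid list was 0.0869. As many lists as the 6 here were called in 74 of 100 splits of the same 10 libraries, the real one included. Immediate early genes had a median of -0.26 (camera adjusted p = 0.0637), and of the circadian clock genes Cry1, a transcriptional repressor, rose (log2 fold change 0.42, limma adjusted p = 0.0449) but passed in 10 of 28 alternatives (limma adjusted p up to 0.239). Neuron, astrocyte, endothelial and mural, meninges and fibroblast, and thalamus lists had camera adjusted p of 0.12, 0.172, 0.172, 0.141 and 0.157.

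Microglia identity genes did not pass as a list in this comparison. Of 24 microglia identity genes 7 had a positive fold change in Model, with a median of -0.15 (camera adjusted p = 0.12, and adjusted p = 0.813 with an estimated correlation). The list score was 3.40 ± 0.22 in Model and 3.54 ± 0.15 in Control (SD, n = 5 each, exact permutation p = 0.29), with Model replicate 3 at 3.78 and the other 4 Model libraries from 3.23 to 3.37. Without Model replicate 3 the median of microglia identity genes was -0.25 and camera called the list lower in Model (adjusted p = 0.00357). Camera also called it lower without Control replicate 4 or 5 (adjusted p = 0.0109 and 0.0487), with array weights (adjusted p = 0.00811) and, in an alternative chosen after seeing the data, without the libraries with low thalamus markers (adjusted p = 0.00554). Tmem119, a marker of resident microglia, stood at 11.4 ± 3.04 FPKM in Control and 7.73 ± 0.75 in Model (limma adjusted p = 0.188), and Cx3cr1 at 15.5 ± 2.06 and 11.997 ± 1.15 (limma adjusted p = 0.268). Aif1, Cd68 and Itgam had limma adjusted p of 0.381, 0.871 and 0.847. The cytokine genes were below the filter: over the 5 libraries of a group, Il1b had 33 reads in Control, 44 in Model and 48 in Minocycline, and Il6 had 5, 18 and 7. Tnf was above 0 in 1 library, Minocycline replicate 4, at 0.0188 FPKM. These 3 genes were not tested. The disease-associated microglia, innate inflammation, interferon response and antigen presentation lists had camera adjusted p of 0.83, 0.466, 0.184 and 0.777.

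The second comparison, Minocycline against Model, asks what minocycline changed under stress. Egr1 (ENSRNOG00000019422), an activity-induced transcription factor, fell from 12.98 ± 1.99 FPKM in Model to 5.85 ± 0.78 in Minocycline (SD, n = 5 each; log2 fold change -1.03, SE 0.11, limma adjusted p = 0.00115). Fkbp5 fell from 29.7 ± 3.23 to 16.3 ± 2.1 FPKM (log2 fold change -0.83, limma adjusted p = 0.0391). These were the 2 genes called of 14509. At an unadjusted p under 0.05 there were 765 genes, against 725 by chance. Egr1 passed in 26 of 28 alternatives, with log2 fold changes from -1.15 to -0.95, and Fkbp5 in 13 of 28, with log2 fold changes from -1.004 to -0.79 (limma adjusted p from 0.000695 to 0.0979 and from 0.0121 to 0.39). Neither passed without the libraries with low thalamus markers or without those with cardiac transcripts, where fewer libraries entered and neither fold change was smaller. Leaving out those with cardiac transcripts kept only Minocycline replicates 1 and 3 in their group, so a call lost there can reflect lower power.

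The genes next by p did not pass. Col1a2, a fibrillar collagen, had a log2 fold change of 1.33 (limma adjusted p = 0.0536), Mfsd2a -0.53, Pcdh20 -0.77, Nr4a1 -1.02, Tmem252 -0.79, Fos -1.04, Mt2A -0.65 and Fgf2 -0.66, with limma adjusted p from 0.216 to 0.303. Vasopressin (Avp) stood at 369 ± 170 FPKM in Model and 757 ± 216 in Minocycline (limma adjusted p = 0.664), and oxytocin (Oxt) at 463 ± 167 and 727 ± 137 (limma adjusted p = 0.745). Crh, which encodes corticotropin-releasing hormone, stood at 4.66 ± 0.72 and 5.18 ± 0.33 FPKM (limma adjusted p = 0.938). Of 30 PVN neuroendocrine genes, 2 were called higher adjusted over the list alone.

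Immediate early genes fell as a list: 21 of 23 had a negative fold change, with a median of -0.47 (camera adjusted p = 5.22e-23, and adjusted p = 0.00503 with an estimated correlation). Adjusted over the list alone, 13 members were called lower. All 5 Minocycline scores lay below every Model score (exact permutation p = 0.0079, the smallest possible, adjusted p = 0.13). Glucocorticoid-responsive genes also fell as a list, with 22 of 23 negative and a median of -0.56 (camera adjusted p = 1.61e-24, and adjusted p = 0.0243 with an estimated correlation). Adjusted over the list alone, 14 members were called lower. Their scores were likewise all below those of Model (exact permutation p = 0.0079, adjusted p = 0.13). Without the libraries with cardiac transcripts the median of this list was -0.28.

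**Figure D2:**
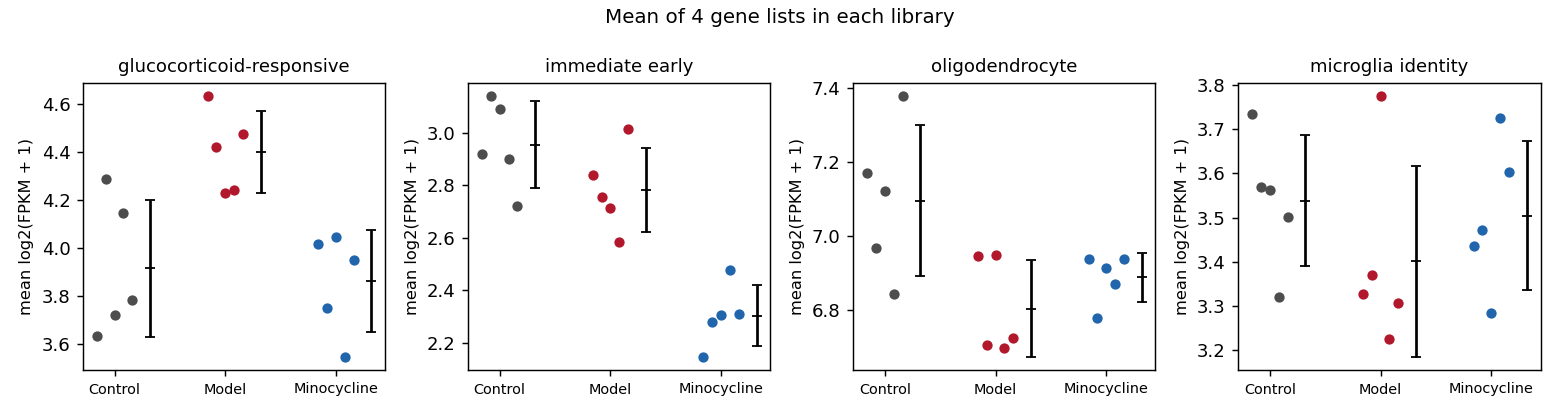
Mean log2(FPKM + 1) of the tested members of 4 fixed lists (y axes, not from 0) in each library, with the mean and SD of 5. The immediate early gene score was 2.95 in Control, 2.78 in Model and 2.30 in Minocycline, and the microglia identity score was 3.54, 3.40 and 3.50.

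Another 7 lists were called by camera and lost with an estimated correlation. PVN neuroendocrine genes (median 0.11) and antigen presentation (median 0.22) then had an adjusted p of 0.705. Meninges and fibroblast genes (median 0.41) and other hypothalamic nuclei (median 0.37) had an adjusted p of 0.627. Neuron (median -0.08), thalamus (median -0.27) and ribosomal protein genes (median 0.08) had adjusted p of 0.408, 0.724 and 0.922. Without the libraries with cardiac transcripts, which left only Minocycline replicates 1 and 3 in their group, none of these 7 lists was called. The medians of PVN neuroendocrine genes and antigen presentation were then -0.0076 and 0.0048 (camera adjusted p = 0.775 and 0.662). Antigen presentation passed in 18 of 28 alternatives, ribosomal proteins and thalamus in 22, PVN neuroendocrine genes in 25, other hypothalamic nuclei in 26, and neuron and meninges and fibroblast genes in 27. The microglia identity list had a median of 0.07 and 17 of 24 genes positive (camera adjusted p = 0.0892, and adjusted p = 0.913 with an estimated correlation). The microglia score differed by 0.10 with an SE of 0.12 (exact permutation p = 0.40), Model replicate 3 standing apart as above. Without it the median was 0.16 and camera called the list higher (adjusted p = 0.00115). Camera also called it higher without Minocycline replicate 2 or 3 (adjusted p = 0.0228 and 0.00354), with only these 2 groups in the fit (adjusted p = 0.0451), with array weights (adjusted p = 0.0236) and without the libraries with low thalamus markers (adjusted p = 0.0107). Its median was -0.0025 without those with cardiac transcripts. As many lists as the 9 here were called in 40 of 100 splits of the same libraries. Oligodendrocyte genes had a median of 0.12 (camera adjusted p = 0.357).

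Whether minocycline moved the stress-associated profile back towards Control was asked by correlating the fold changes of both comparisons across genes, which are not independent replicates. The correlation was -0.48, and random deals of the libraries, which share the Model libraries in the same way, gave a mean of -0.48. The covariance was -0.0173 against -0.0144 by chance. With the Model libraries divided between both fold changes the correlation was -0.047 (SD 0.092 over 20 divisions), and 34 of 100 deals gave a value as low. Of the 53 genes called in Model against Control, 45 had the opposite sign in Minocycline against Model, which shares the Model libraries. Calling with 3 Model libraries gave 3 to 128 genes over 10 splits. Of these, 46.1% to 100% had the opposite sign with the 2 other Model libraries. All 53 kept their sign in Minocycline against Control, which shares the Control libraries. No chance value was computed for these counts.

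The third comparison, Minocycline against Control, called 17 genes, 7 higher and 10 lower in Minocycline, and 1643 genes had an unadjusted p under 0.05. Egr1 (log2 fold change -1.38, limma adjusted p = 1.77e-05), Fos (-1.56, limma adjusted p = 0.00479), Nr4a1 (-1.51) and Junb (-1.02) were lower, as were Btg2, Tjap1, Tmem151b, Jun and Hdac5. Fos stood at 12.1 ± 1.31 FPKM in Control and 3.51 ± 0.91 in Minocycline (SD, n = 5 each). Rbm3 was higher at 1.04 (limma adjusted p = 0.00479), from 32.6 ± 5.36 to 68.1 ± 10.5 FPKM, followed by Mt2A at 0.88, Chchd7 at 0.81, Sema3g at 0.64, Eid2b at 0.47 and Ufd1l at 0.37. Egr1 passed in all 28 alternatives, Rbm3 in 27, Mt2A in 26, Chchd7 in 14, Btg2 and Tjap1 in 15, Eid2b in 16, Hdac5 in 19, Jun in 20 and the other 6 in 25. Without the libraries with cardiac transcripts, with only Minocycline replicates 1 and 3 left in their group, 2 genes were called. Without those with low thalamus markers 4 were called. The count was 9 without Control replicate 3, 10 without Control replicate 4 or Minocycline replicate 5, and 11 without Minocycline replicate 1 or 2.

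Of 23 immediate early genes 21 had a negative fold change against Control, with a median of -0.63 (camera adjusted p = 3.76e-20, and adjusted p = 0.00843 with an estimated correlation). Over all genes 6 members were called lower, and 19 adjusted over the list alone. Nuclear oxidative phosphorylation subunits (median 0.13), ribosomal proteins (0.17), oxidative stress response (0.07) and antigen presentation (0.17) were called higher by camera. Oligodendrocyte (-0.17), oligodendrocyte precursor (-0.27) and heat shock genes (-0.13) were called lower. All 7 had an adjusted p of 0.706 with an estimated correlation. In the order given they passed in 28, 27, 25, 18, 26, 22 and 26 of 28 alternatives. Without the libraries with cardiac transcripts the medians of the 4 higher lists were 0.049, 0.025, 0.020 and 0.0076, and only oxidative phosphorylation was called. That setting, with Minocycline replicates 1 and 3 alone in their group, called 3 lists lower, among them immediate early and microglia identity genes. Most of the oligodendrocyte, oligodendrocyte precursor and heat shock lists thus lost their call there. Over all alternatives the oligodendrocyte and oligodendrocyte precursor medians reached -0.055 and -0.044 (camera adjusted p up to 0.411 and 0.213). Minocycline replicate 5 had the highest scores for oxidative phosphorylation (6.75) and ribosomal proteins (7.59), and Minocycline replicate 4 for antigen presentation (3.22). Glucocorticoid-responsive genes had a median of -0.13 (camera adjusted p = 0.802) and microglia identity genes of -0.01 (camera adjusted p = 0.65, and adjusted p = 0.0399 towards lower without the libraries with cardiac transcripts). As many lists as the 8 here were called in 51 of 100 splits.

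Both comparisons against Control share the Control libraries. They had 4 genes called higher and 3 called lower in common. Independent lists would share 0.015 in each direction, but the shared Control libraries make these lists dependent. The 100 deals shared 0, but they hold no effect from which genes could be called. Neither value is therefore a chance level for this overlap. With the Control libraries divided between both comparisons no gene was called in both. Each comparison then held fewer Control libraries, and its own number of calls was not kept, so this cannot judge the overlap. The correlation of fold changes across genes was then 0.27, for which no chance value was computed. Undivided it was 0.63, where the deals gave a mean of 0.49, and the undivided covariance exceeded its mean over the deals by 0.0107. The spread over the deals was not kept, so neither excess can be judged against chance.

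Markers of neighbouring tissue differed between libraries of the same group. The thalamus score was 2.91 and 3.83 in Control replicates 1 and 5, 3.23 in Model replicate 3, and 3.65 and 3.50 in Minocycline replicates 2 and 4, against 4.43 or more in the other libraries. In the same order, these libraries had the highest PVN neuroendocrine scores, 4.92, 4.95, 4.99, 4.997 and 5.09, against at most 4.88 in the others. Leaving them out therefore kept the libraries with more thalamus and less PVN marker transcript, and was no removal of off-target tissue. Prkcd, a thalamic kinase gene, ranged from 6.74 to 179 FPKM. Across the 15 libraries the thalamus score followed the first principal component (22.9% of variance; Pearson r = 0.88, permutation p = 4e-05; Spearman rho = 0.80, permutation p = 0.00055; r = 0.84 without the 2 libraries farthest from the median). Cardiac muscle transcripts, a list added after the values were seen, summed to 103, 160 and 124 FPKM in Minocycline replicates 2, 4 and 5 and to 42.1 in Model replicate 2, against at most 30.7 in the other 11 libraries.

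**Figure D3:**
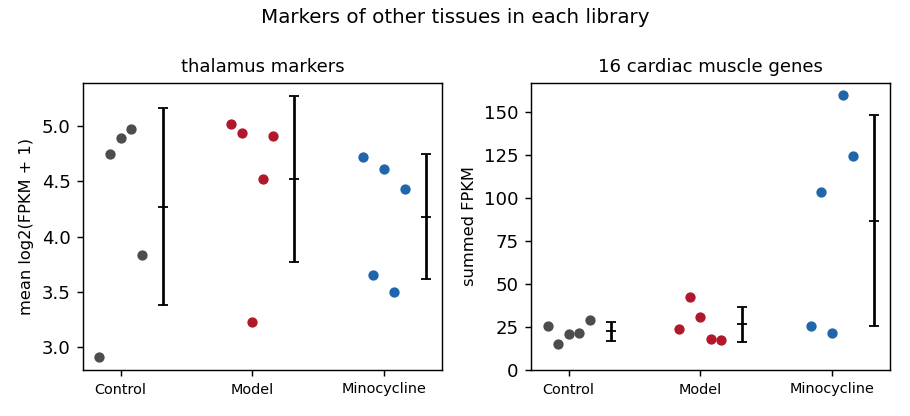
Mean log2(FPKM + 1) of 11 thalamus markers (left, y axis not from 0) and summed FPKM of 16 cardiac muscle genes (right, y axis from 0) in each library, with the mean and SD of 5. Low thalamus scores occur in each group, and cardiac sums above 100 FPKM occur in 3 Minocycline libraries.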

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

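In groups of 5 libraries, a library was singled out when its gap to the nearest other exceeded 0.71 of the group's range. Of 240 groups tested 18 met this, and chance gives about 12 at 1 in 20. The tests of explanations in this part were chosen after the results were seen.

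Model replicate 3 was high in the scores of microglia identity (3.78), innate inflammation (2.34), endothelial and mural (3.84) and meninges and fibroblast genes (3.75), and low in the thalamus score (3.23). Its log2(FPKM + 1) of Slco2b1 was high (3.64). Model replicate 1 was high in choroid plexus genes (4.13). Minocycline replicate 4 was high in antigen presentation (3.22), interferon response (2.53) and endothelial and mural genes (3.97), and its log2(FPKM + 1) of Tnf was 0.0269. Minocycline replicate 5 was high in nuclear oxidative phosphorylation subunits (6.75) and Cryab (6.17, all gene values here being log2(FPKM + 1)). Minocycline replicate 1 was high in Pcdh20 (3.87) and low in Nr4a1 (1.46). Control replicate 1 was high in renin-angiotensin and adrenergic genes (3.07) and Col1a2 (1.99), and Control replicate 5 was low in Lrg1 (1.32).

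The lower immediate early genes in Minocycline than in Model differed by -0.48 in list score (SE 0.09). With the thalamus score in the fit the difference was -0.46, without the libraries with cardiac transcripts -0.56, and the neuron score differed by -0.10, which argues against each of these as the whole cause. All 5 Minocycline libraries lay below every Model library. Minocycline may account for this, but any difference in handling or timing between the groups, of which the labels say nothing, cannot be told apart from it.

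The glucocorticoid-responsive score was 0.48 higher in Model than in Control (SE 0.14), and 0.43 with the thalamus score in the fit. It was 0.54 lower in Minocycline than in Model, at -0.54 as fitted and -0.46 with the thalamus score, so a different share of thalamus is not the whole cause. The median of the list was less firm: 0.39 in Model against Control became 0.28 with that covariate and 0.23 without the libraries with low thalamus markers. Without the libraries with cardiac transcripts the Minocycline difference was -0.36 (SE 0.20), too wide to decide. Stress may account for the rise, but 3 of 5 Model libraries lay above every Control library, and any difference in handling between the groups stays open.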

How the results depend on the processing

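Alternatives on recovered reads (voom), thalamus and left-out groups were chosen after seeing the data, as was the limit for the splits. All 53, 2 and 17 genes called kept their sign in each setting. Of gene and list values, 13620 kept direction and side of the threshold, 342 lost it and 116 gained it. Direction turned in 279 uncalled values and 4 with a call. The cause was not tested except where fewer libraries or other genes show it.

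For Model against Control, the count of 53 genes became 28 with a filter at 0.1 FPKM, 28 with no filter, 20 with only the 2 groups in the fit, 223 with array weights, 90 with the thalamus score as covariate, 33 leaving out the low-thalamus libraries and 14 leaving out the cardiac-transcript libraries. Voom called 37. Leaving out single libraries gave 19 to 195. For Minocycline against Model, 2 genes became 1 with either other filter, 1 with quantile normalization, 4 with array weights, and 0 leaving out the low-thalamus or the cardiac-transcript libraries, with fewer libraries and no smaller folds of Egr1 and Fkbp5. Single libraries gave 1 to 3. For Minocycline against Control, 17 became 86 with array weights, 42 with the thalamus covariate, 4 and 2 leaving out the low-thalamus and cardiac-transcript libraries, and 9 to 21 over single libraries. Quantile normalization gave 14 higher and 11 lower, against 7 and 10.

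A replicate block gave 10, 2 and 3 genes, and no list count moved by over 1.5 times. Of 15 same-number correlations, 1 exceeded 0.1 and 1 was the best for its library. Tissue differences could hide pairing, so why the block lost calls stays open.

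The counts of 6, 9 and 8 lists became 0, 2 and 1 by camera with estimated correlation, and 0, 2 and 1 by fry. Leaving out the cardiac-transcript libraries, which kept only Minocycline replicates 1 and 3 in their group, gave 3 lists for Minocycline against Model. It gave 4 for Minocycline against Control. Over single libraries, lists ranged 4 to 11, 5 to 13 and 6 to 10. In Minocycline against Model, leaving out the cardiac-transcript libraries turned the medians of the glutamate and GABA list to 0.098 (called) and, uncalled, of thalamus to 0.29, PVN neuroendocrine genes to -0.0076 and ribosomal proteins to -0.00011. Over single libraries, oxidative phosphorylation ranged from -0.035 without Minocycline replicate 5 (called lower) to 0.11 without Model replicate 2, and cytosolic ribosomal proteins from 0.016, where camera pointed lower uncalled, to 0.16 without the same libraries.

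The correlation of -0.047 with divided Model libraries became 0.026 leaving out the low-thalamus libraries and 0.058 leaving out the cardiac-transcript libraries. Over single libraries it ranged from -0.21 without Model replicate 3 to 0.039 without Model replicate 5, and was 0.015, 0.011 and 0.022 without Control replicate 1, Model replicate 1 and Model replicate 2.

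Of 100 splits of the 10 libraries, the real one included, 1 gave as many genes as Model against Control (53, highest other 1). Minocycline against Control had 2 (17, highest other 123) and Minocycline against Model 5 (2, highest other 260). The limit of 5 in 100, set after seeing the data, cannot exclude chance. The split calling 260 set Minocycline replicates 2, 4 and 5 and Model replicates 2 and 3 apart, and that calling 123 set Control replicates 1 and 5 and Minocycline replicates 2, 4 and 5. These are libraries with low thalamus markers or cardiac transcripts. A split calling 110 genes, with Minocycline replicate 1 in place of 2 in the first, follows them less closely. Such splits point to structure other than the groups. As many lists were called in 74, 40 and 51 of 100 splits (6, 9 and 8, highest others 21, 22 and 20), so chance is not excluded for these counts. Scores of single lists were compared over regroupings by the exact permutation tests, in which none had an adjusted p below 0.05.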

Other observations

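The genes named here, the comparison of cardiac sums between Minocycline and Control and the count of heart genes one by one were chosen after the values were seen. S100a8 and S100a9, neutrophil genes of the infiltrating leukocyte list, reached 72.9 and 117 FPKM in Minocycline replicate 4, against at most 4.001 and 6.9998 in Model and 1.30 and 3.24 in Control. This library also had the most haemoglobin transcript (Hba1 1276 FPKM, the others at most 599) and the highest blood cell score (6.21). Control replicate 5, next in Hba1 at 599 FPKM, had 0.686 and 0 FPKM of S100a8 and S100a9. Whether blood left in the tissue brought the neutrophil genes or the high antigen presentation score of Minocycline replicate 4 was not tested. Cga, the glycoprotein hormone alpha subunit made in the pituitary, ranged from 0 to 324 FPKM, and Tshb, a pituitary hormone subunit, from 1.197 to 52.2. The pituitary list had camera adjusted p of 0.184, 0.587 and 0.381 in Model against Control, Minocycline against Model and Minocycline against Control. The 13 mitochondrially encoded genes, a list added after the values were seen, took between 6.34% and 10.4% of reads. All 13 had a positive fold change in Minocycline against Control (median 0.29) and in Model against Control (median 0.15), and 11 in Minocycline against Model (median 0.13), with no gene called. The score differed by 0.29 in Minocycline against Control (SE 0.09, exact permutation p = 0.0079, adjusted p = 0.085), and the other comparisons had exact permutation p of 0.15 and 0.37.

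Cardiac muscle transcripts stood out in 3 Minocycline libraries and 1 Model library. The list was drawn up after this was seen, while the test on the sum of other heart genes was written before its result. Nppa was 82.8 FPKM in Minocycline replicate 4, against 24.4 in replicate 5, while Mb was 7.24 and 19.4. Minocycline replicates 1 and 3 summed to 25.6 and 21.3 FPKM, inside the Control range of 15.1 to 29.2, so the sum did not rise in every Minocycline library. This restates the pattern that prompted the list and is no test of a response to minocycline. RNA or reads from heart may be the source, and the test written for it left this open: of 12 other heart genes 11 had a row, and their sum exceeded each of the 11 other libraries in 2 of the 4. Casq2, part of that sum, was seen in every library. Counted gene by gene, a choice made after that result, 4 of the 11 (Myom2, Xirp2, Mylk3 and Myoz2) were higher in all 4 libraries than in each other library, where 0.0081 genes would be expected for any 4 libraries. This second count was made on the same data and decides nothing.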
